A study of Mus musculus with 9 samples.

How the data were processed

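Total RNA of bone-marrow-derived macrophages was extracted with the mirVana kit, amplified to cRNA, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. Images were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The background correction and the software behind the normalization are not given in the sources used here. The value table that the authors deposited holds log2 signals of 117341 spots on 9 arrays. Every array holds exactly the same set of values (largest difference between sorted arrays 0), so the deposited log2 values were quantile normalized between arrays. No detection flags, background values, slide positions or dates were used here, and signal over background is unknown.

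The value table names no genes. A second table, of 14289 rows, pairs values with gene symbols, transcript identifiers and coordinates. Each of its rows equals 1 probe of the value table in all 9 arrays within 1e-06, and names were carried over by that match. Tested on the file, all 14289 rows have a fold of 1.5 or more and an unadjusted p under 0.05 in at least 1 of the 3 pairwise comparisons by an equal-variance test. Of all probes, 21426 meet that rule. The deposited p-values of that table, and its signed fold column, refer to metformin with high glucose against untreated cells: the p-value equals that comparison in 14289 rows and the fold in 14202 (within 0.001). The authors' deposited values give 689 rows with both a fold of 1.5 and a p under 0.05 in that comparison, and 8586 rows are marked up and 5703 down. Symbols were looked up in a RefSeq table of assembly GRCm38.p6, which held 4703 of 4896, for gene type and for a comparison of coordinates. The letters inside probe names, which seem to mark classes, are not explained in the sources used here and were not used.

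Groups follow the treatment in the labels, 3 arrays each. Nothing says whether replicates were separate cultures or animals, so p-values measure the spread between these arrays, which may be technical. The 68 control spots were left out of the tests. Probes with a mean under the 25th percentile (1.46) were left out, leaving 87955. All 9 arrays entered one linear model on the group (limma 3.58.1 in R 4.3.3, eBayes without trend, prior degrees of freedom 1.52 beside 6 residual), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. It had been fixed before the data were examined that each gene would take its brightest probe over the whole table. Since only part of the probes have names, the test was run over all probes, and a named gene takes the values and adjusted p of its brightest named probe. Of 2719 genes with several named probes, 22 had probes that passed in opposite directions with high glucose.

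A low-signal level of 4 was set after the data were seen, because the median SD within groups is 0.464 at means of 3 to 4 and 0.298 at 4 to 5, against 0.098 at 8 to 12. Where all 3 arrays of one group lie under 4, a fold is given as "at least", the bright group's mean against that level. Other folds are 2 to the difference of mean log2 values.

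Before the data were examined, 27 gene lists with 750 distinct genes were fixed, for cytosolic DNA sensing, inflammasomes, macrophage activation, metabolism, stress responses and markers of marrow cell types. Of these genes 368 are in the named table and the others were not analysed here. Lists with 5 or more named genes, 25 in all, were tested among the named genes with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over lists. The genes named in the text were fixed by a rule before the data were examined: per main comparison the 8 largest rises and 8 largest falls past the threshold with arrays that do not overlap, up to 4 members per list with the largest absolute change, and 10 genes of pyroptosis and DNA sensing. Exceptions are marked, apart from Csf1 and Csf3r, the single members that went against their lists, which were named after their values were seen. Some genes that the rule selects are not reported here. The reversal by metformin was set against 100 simulations of unchanged groups.

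The model was tested on simulated data made from the real probe means and spreads of 87955 probes with 200 changed. For high glucose against untreated, 32% of 2-fold, 54% of 4-fold and 76% of 8-fold changes were recovered. At a mean of 4 or more, 55.2% of 2-fold and 82.8% of 4-fold changes were. For metformin against untreated, 26%, 60% and 86% were recovered, and 50% of 2-fold and 92.9% of 4-fold changes at a mean of 4 or more. With 21989 probes changed 2-fold between high glucose and untreated, 70.7% were recovered and 3.88% of calls were false. With 200 changed, 3 of 84 calls were false for high glucose against untreated, 8 of 98 for metformin against high glucose and 8 of 95 for metformin against untreated.

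Alternatives fixed before the data were examined were quantile normalization, median centring, no filter and a filter at the 50th percentile, the mean over a gene's probes and every probe on its own, a variance trend with robust estimation, array weights, fits of 2 groups, the replicate number as a block, each array left out, and thresholds with a fold of 2. Cyclic loess and a filter on the highest group mean were added later.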

Results

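Gene expression was measured on one-colour arrays in mouse bone-marrow-derived macrophages, which are primary macrophages grown from marrow precursors. The labels give 3 groups of 3 arrays each: untreated cells, cells under high glucose, and cells under high glucose with metformin, a biguanide used to lower blood glucose. Glucose and metformin doses and exposure times are not given in the sources used here. The series title names diabetes, macrophage dysfunction, cytoplasmic double-stranded DNA and pyroptosis through AIM2, so the comparisons ask how high glucose changes the macrophage transcriptome and what metformin does to that change. Each array held 117273 probes besides 68 control spots, on a log2 scale on which the 9 arrays have the same distribution, with a median of 3.49 and quartiles of 1.29 and 6.72. Genes could be named for 14289 probes, which stand for 4896 gene symbols. The authors' deposited table that pairs them holds probes that already differed between groups on these same arrays. Counts over named genes, and counts and tests over lists of them, are therefore not independent evidence. Counts over all 87955 tested probes stand beside the counts over named genes. List tests with camera rank members against the other named genes. The median log2 change of named genes was -0.44 with high glucose and 0.274 with metformin against high glucose. Over all tested probes it was -0.021 and 0.015. Lists are counted by their named members alone, such as 14 of the 34 genes fixed for lysosomes and autophagy. For NRF2 and oxidative stress these are 13 of 28, for neutrophil markers 6 of 22, and for interferon-stimulated genes 32 of 39. The high-glucose arrays stood apart from the other 6: across probes, they correlated with untreated arrays at 0.938 to 0.95, against 0.978 to 0.98 between untreated arrays and 0.97 to 0.977 between untreated and metformin arrays. High-glucose arrays correlated with each other at 0.963 to 0.971, so that group was looser than the untreated one. The number of arrays limits the precision of every value, and the labels name no osmotic control, no vehicle control and no group with metformin alone.

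High glucose was accompanied by a large inflammatory change. Il1b, which encodes the cytokine interleukin-1 beta, rose from 3.07 ± 1.77 to 15.4 ± 0.455 on the log2 scale (SD, n = 3), a log2 difference of 12.38 (SE 0.834, adjusted p = 3.54e-05), whose size is uncertain because 2 of the 3 untreated arrays lay under the low-signal level of 4. Nos2, the inducible nitric oxide synthase, rose at least 107-fold, counted from the low-signal level under which all 3 untreated arrays lay. The inflammasome sensor Nlrp3 rose from 6.09 ± 0.029 to 10.4 ± 0.139 (SD, n = 3), or 20.4-fold. In the other direction, Pparg, a nuclear receptor of lipid metabolism and alternative macrophage activation, fell by 3.69 on the log2 scale (SE 0.184, adjusted p = 8.10e-06), and Pcp4l1, a small calmodulin-regulator-like protein, fell at least 21.8-fold.

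Of 87955 probes, 10365 were higher and 11806 lower in high glucose than in untreated cells (limma, adjusted p under 0.05), together 25.2% of those tested, while cyclic loess scaling, tried after the data were seen, turned the balance to 11856 higher and 10476 lower. Among the 4896 named genes, 1949 rose and 2117 fell. With a fold of 2 or more required as well, 4225 probes were higher and 4447 lower. In 42.4% of the probes the 3 arrays of one group did not overlap the 3 of the other, where chance gives 10%. Besides Il1b and Nos2, given above, the rises that the naming rule selects by log2 difference took in Cxcl2 (at least 384-fold) and Cxcl3 (at least 139-fold). Both are neutrophil-attracting chemokines. The others were the iron-binding lipocalin Lcn2 (9.95 on the log2 scale, SE 0.317), the scavenger receptor Marco (8.11, SE 0.234), Tarm1 (7.67, SE 0.426), a receptor of myeloid cells, and Tnfaip6 (at least 23.9-fold), a hyaluronan-binding protein. Marco and Tarm1 had 1 untreated array each above the low-signal level of 4, and Il1b also had 1. That difference also ranks values under the low-signal level, for which only the bounds hold. The falls it selects, after Pcp4l1, were in Mamdc2 (at least 21.3-fold), the cyclin-dependent kinase inhibitor Cdkn1c (at least 5.65-fold), the integrin subunit Itgb3 (at least 4.92-fold), Nanos1 (at least 3.91-fold), the organic anion transporter Slco2b1 (at least 2.98-fold), Slc24a3 (at least 2.42-fold) and Tpbgl (at least 2.17-fold). Several of these bounds are smaller than the falls of Pparg (12.9-fold) and Lpl (10.5-fold). Both group means of Lpl lay well above the level, but Pparg in high glucose lay at it (4.03 ± 0.355, SD, n = 3).

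**Figure D1:**
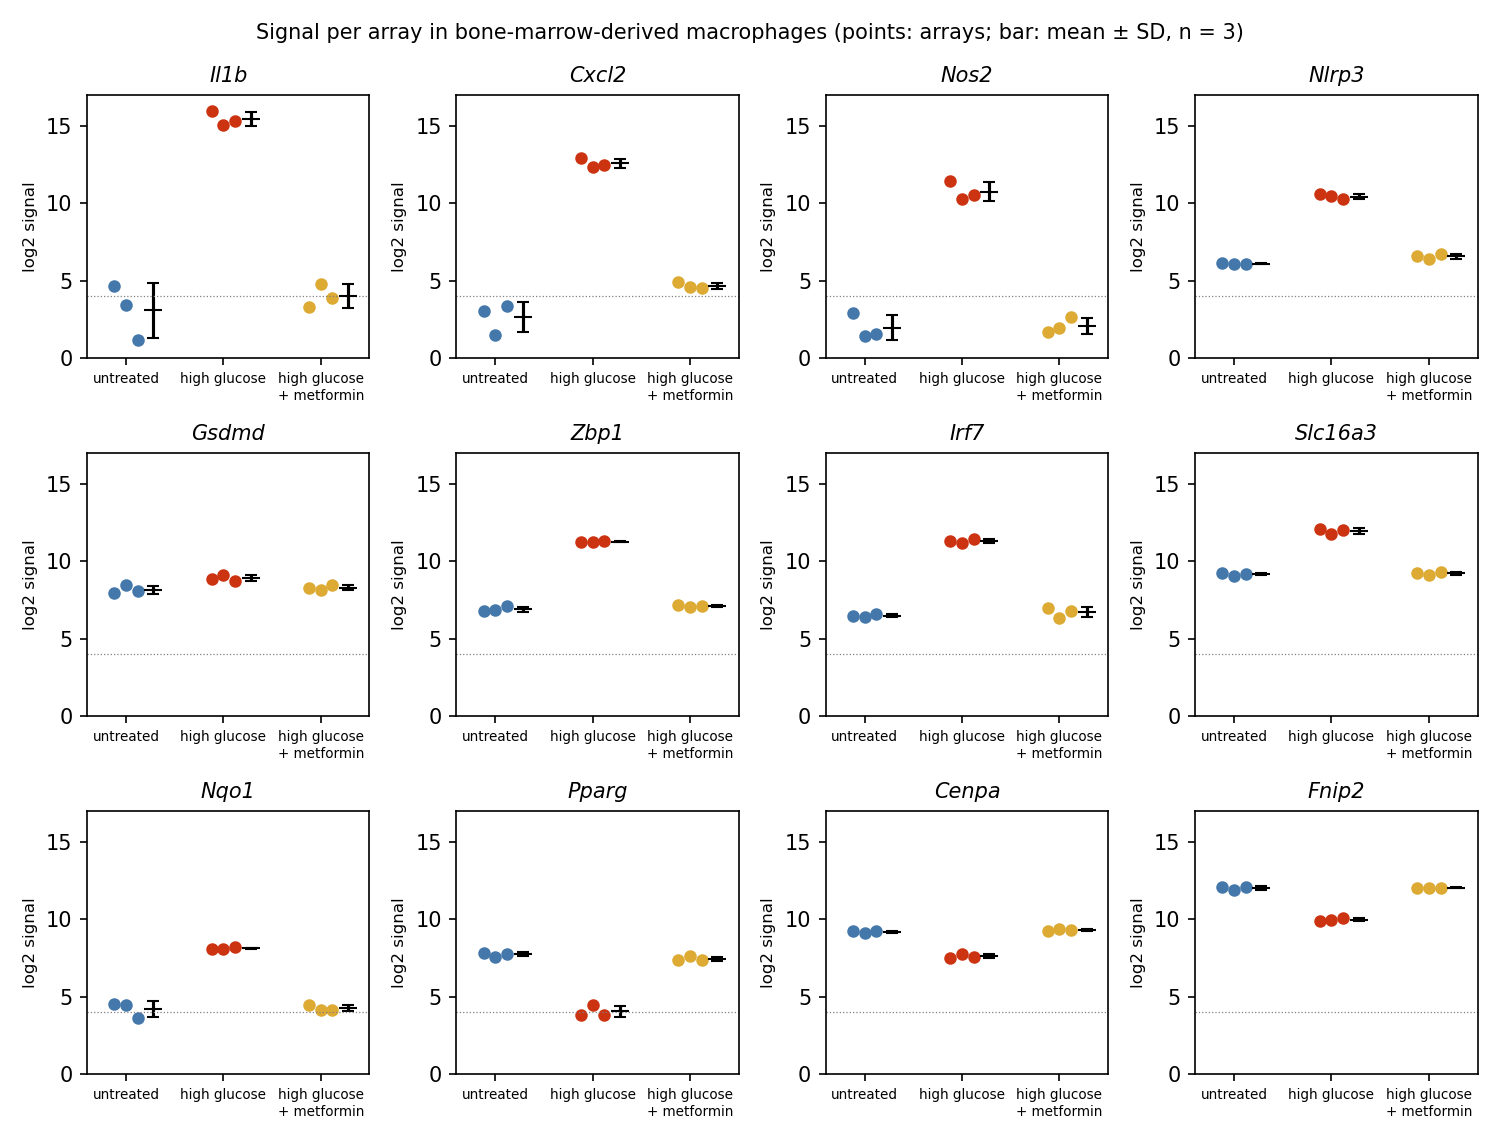
Log2 signal (y axis) of 12 named genes in each of the 9 arrays, by group (x axis), with points for arrays, black bars for the mean and SD of 3 arrays, and a dotted line at the low-signal level of 4. Il1b had a mean of 15.4 in high glucose against 3.07 untreated and 3.99 with metformin, while Pparg had 4.03 in high glucose against 7.72 and 7.43.

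For the genes that the series title points to, the named table held 3 of the 10 chosen in advance. Il1b and Nlrp3 are given above. Gsdmd, the gasdermin whose cleaved form opens membrane pores in pyroptosis, rose from 8.15 ± 0.248 to 8.91 ± 0.194 (SD, n = 3), a 1.7-fold change (adjusted p = 0.0124). Aim2, Casp1, Il18, Pycard, Cgas, Sting1 and Txnip were not analysed here. The list for cytosolic DNA sensing and AIM2 had 10 named members, of which 6 rose and 4 fell. The nucleic acid sensor Zbp1 rose 20.7-fold (log2 change 4.37, SE 0.107) and Pyhin1, of the same interferon-inducible family as AIM2, rose 3.09-fold. Nlrc3, a negative regulator of innate signalling, fell by 2.25 and Enpp1, which degrades the second messenger cGAMP, fell by 1.62 on the log2 scale. Probe sequences were not used here, so values of Pyhin1 and its close relatives, like those of other multigene families, are uncertain. The inflammasome and pyroptosis list had 15 named members, of which 10 rose and 5 fell, among them Il1a (32.7-fold higher) and Gbp5 (at least 13.9-fold higher). Neither list passed the test against the other named genes (camera adjusted p = 0.44 and 0.0854).

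Interferon-stimulated genes rose throughout: 32 of 32 named members passed, led by the transcription factor Irf7 (28.3-fold), Ifit1 (26.4-fold), Ifit3 (11.9-fold) and the deISGylating protease Usp18 (11.4-fold). Ifit3 had an untreated mean of 3.92, under the low-signal level, so its fold is uncertain. The list moved up against the other named genes (camera adjusted p = 4.17e-11, but adjusted p = 0.121 with an estimated correlation). Of 27 named cytokines, chemokines and related inflammatory genes, 26 rose and 1, Csf1, fell (camera adjusted p = 4.78e-09, and adjusted p = 0.12 with an estimated correlation). Of 18 immediate-early and heat-shock genes, 14 rose and 3 fell, with Nr4a2 at 23.8-fold, the NF-κB target Ier3 at 15.2-fold, the phosphatase Dusp1 at 10.8-fold and Fos at 7.69-fold (camera adjusted p = 0.00168, and adjusted p = 0.231 with an estimated correlation). Of 13 genes of antigen presentation, 11 rose and 1 fell. The immunoproteasome subunits Psmb10 (3-fold) and Psmb8 (2.59-fold), the loading chaperone Tapbp (2.7-fold) and the class II gene H2-Ab1 (2.52-fold) rose most (camera adjusted p = 0.00622, and adjusted p = 0.274 with an estimated correlation).

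Metabolic and stress-response genes moved as well. Of 27 genes of glycolysis and glucose uptake, 20 rose and 4 fell. The lactate exporter Slc16a3 rose 6.92-fold, the glucose-responsive arrestin Arrdc4 6.15-fold, the regulatory kinase Pfkfb3 4.79-fold and the phosphofructokinase Pfkp 4.01-fold (camera adjusted p = 0.00168, and adjusted p = 0.231 with an estimated correlation). All 13 named NRF2 and oxidative-stress genes rose, including the quinone reductase Nqo1 (15.2-fold), the mitochondrial superoxide dismutase Sod2 (13.6-fold) and glutathione reductase Gsr (3.2-fold). That list had the lowest adjusted p with an estimated correlation, 0.0755 (camera adjusted p = 4.79e-05). Of 16 hypoxia-response genes, 13 rose and 3 fell. Vegfa was 12-fold and Hif1a 4.91-fold higher (camera adjusted p = 0.00628, and adjusted p = 0.274 with an estimated correlation). Of 11 ATF4 and amino acid response genes, out of 40 fixed, 9 rose and 2 fell. The glycine transporter Slc6a9 rose at least 17.9-fold and the cystine transporter Slc7a11 8.27-fold (camera adjusted p = 0.0191, and adjusted p = 0.183 with an estimated correlation). Of 14 chaperone genes of the unfolded protein response, 12 rose and 1 fell, by modest amounts, with Hyou1 at 1.88-fold (camera adjusted p = 0.0106, and adjusted p = 0.274 with an estimated correlation). Of 39 fixed nuclear genes of oxidative phosphorylation, only 6 were in the named table, which holds changed probes, and those 6 rose, such as Atp5o (1.9-fold) and Cox5a (1.84-fold) (camera adjusted p = 0.0242, and adjusted p = 0.231 with an estimated correlation). Of 8 cholesterol synthesis genes, out of 25 fixed, 7 rose and 1 fell (camera adjusted p = 0.0641).

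The lists that fell were those of division and lysosomes. Of 30 cell-cycle genes, 26 fell, none rose and 4 did not pass. Nusap1 fell by 1.81, Cenpf by 1.58 and the centromeric histone Cenpa by 1.58 on the log2 scale (camera adjusted p = 4.79e-05, and adjusted p = 0.231 with an estimated correlation). Of 14 lysosome and autophagy genes, out of 34 fixed, 12 fell and 1 rose. The folliculin partner Fnip2 fell by 2.05, the GTPase Rragd by 1.86 and Tfeb itself, the regulator of the list, by 1.27 (camera adjusted p = 0.00628, and adjusted p = 0.183 with an estimated correlation).

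Other lists split. Of 17 genes of alternative activation, 8 rose and 8 fell, with Klf4 13.1-fold higher and Pparg lower. Of 22 phagocytosis and scavenger receptor genes, 9 rose and 13 fell: complement C3 was 15.4-fold, Tlr2 14.1-fold and the lipopolysaccharide co-receptor Cd14 8.94-fold higher, while Itgb3 was lower. Of 18 genes of LXR targets and lipid handling, 6 rose and 11 fell. Dgat2 and Dgat1, the enzymes of triglyceride synthesis, were at least 3.77-fold and 6.7-fold higher, Acsl1 was 9.11-fold higher, and lipoprotein lipase Lpl fell by 3.39 on the log2 scale. Of 17 p53 and DNA damage genes, 6 rose and 9 fell, with the death receptor Fas 19.9-fold and Cdkn1a 4.39-fold higher and Sesn1 lower by a log2 change of -2.27. None of these 4 passed the list test (camera adjusted p between 0.354 and 0.985). Of 3 ribosomal protein genes, 1 rose and 2 fell, Rpl4 by 0.57 on the log2 scale, and no list test was run on 3 genes. The rise of Rps20 and the fall of Rps24 lost their calls without single arrays (limma adjusted p up to 0.0761 and 0.0998).

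Markers of cell types moved with the same contrast. Of 16 macrophage identity genes, 7 rose and 9 fell, with Cd14 higher and Cebpa and Lgals3 lower by log2 changes of -2.5 and -2 (camera adjusted p = 0.733). Of 6 neutrophil markers, 5 rose and 1, the granulocyte receptor Csf3r, fell. Lcn2, which the cytokine list also holds, Mmp9 (at least 23.3-fold) and S100a8 (26.1-fold) rose most (camera adjusted p = 0.0265, and adjusted p = 0.231 with an estimated correlation). Of 7 lymphocyte markers, 5 rose and 1 fell, among them Gzmb (2.82-fold) and, at low signal, Nkg7 (at least 1.32-fold). Of 5 mast cell, basophil and eosinophil markers, Hdc rose and 4 fell, including Ccr3 by 1.62 on the log2 scale. Of 6 stromal markers, 2 rose and 3 fell, and Cxcl12 fell by 0.81. The rise of Timp1 and the fall of Col1a2 lost their calls without single arrays (limma adjusted p up to 0.114 and 0.0585). Of 6 erythroid and megakaryocyte markers, 1 rose and 3 fell, and Vwf fell by 0.97. The rise, in Klf1, lost its call without untreated or high-glucose replicate 1 or 3 (limma adjusted p up to 0.084). These 4 lists did not pass (camera adjusted p between 0.0866 and 0.733). Of 3 dendritic cell markers, Bst2, which interferon also induces, rose 4.36-fold, and Siglech and Itgax fell.

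Adjusted over the list alone, the lists with a different number of members past the threshold were glycolysis (26 of 27), LXR and lipid handling (18 of 18), chaperones (14 of 14), p53 (17 of 17), cell cycle (28 of 30), immediate-early genes (18 of 18), lymphocyte markers (7 of 7), and erythroid markers (5 of 6). With camera's preset correlation of 0.01, 11 lists moved up and 2 down out of 25, and with an estimated correlation none passed. List members and the genes they were ranked against were all chosen for differing on these arrays, which limits both results. Median, mean and test differed in sign for alternative activation (median 0.18, mean 0.15, test down), for p53 (median -0.62, mean 0.02, test down) and for erythroid markers (median -0.16, mean 0.15, test down). The mast cell list went down by camera and up by fry.

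**Figure D2:**
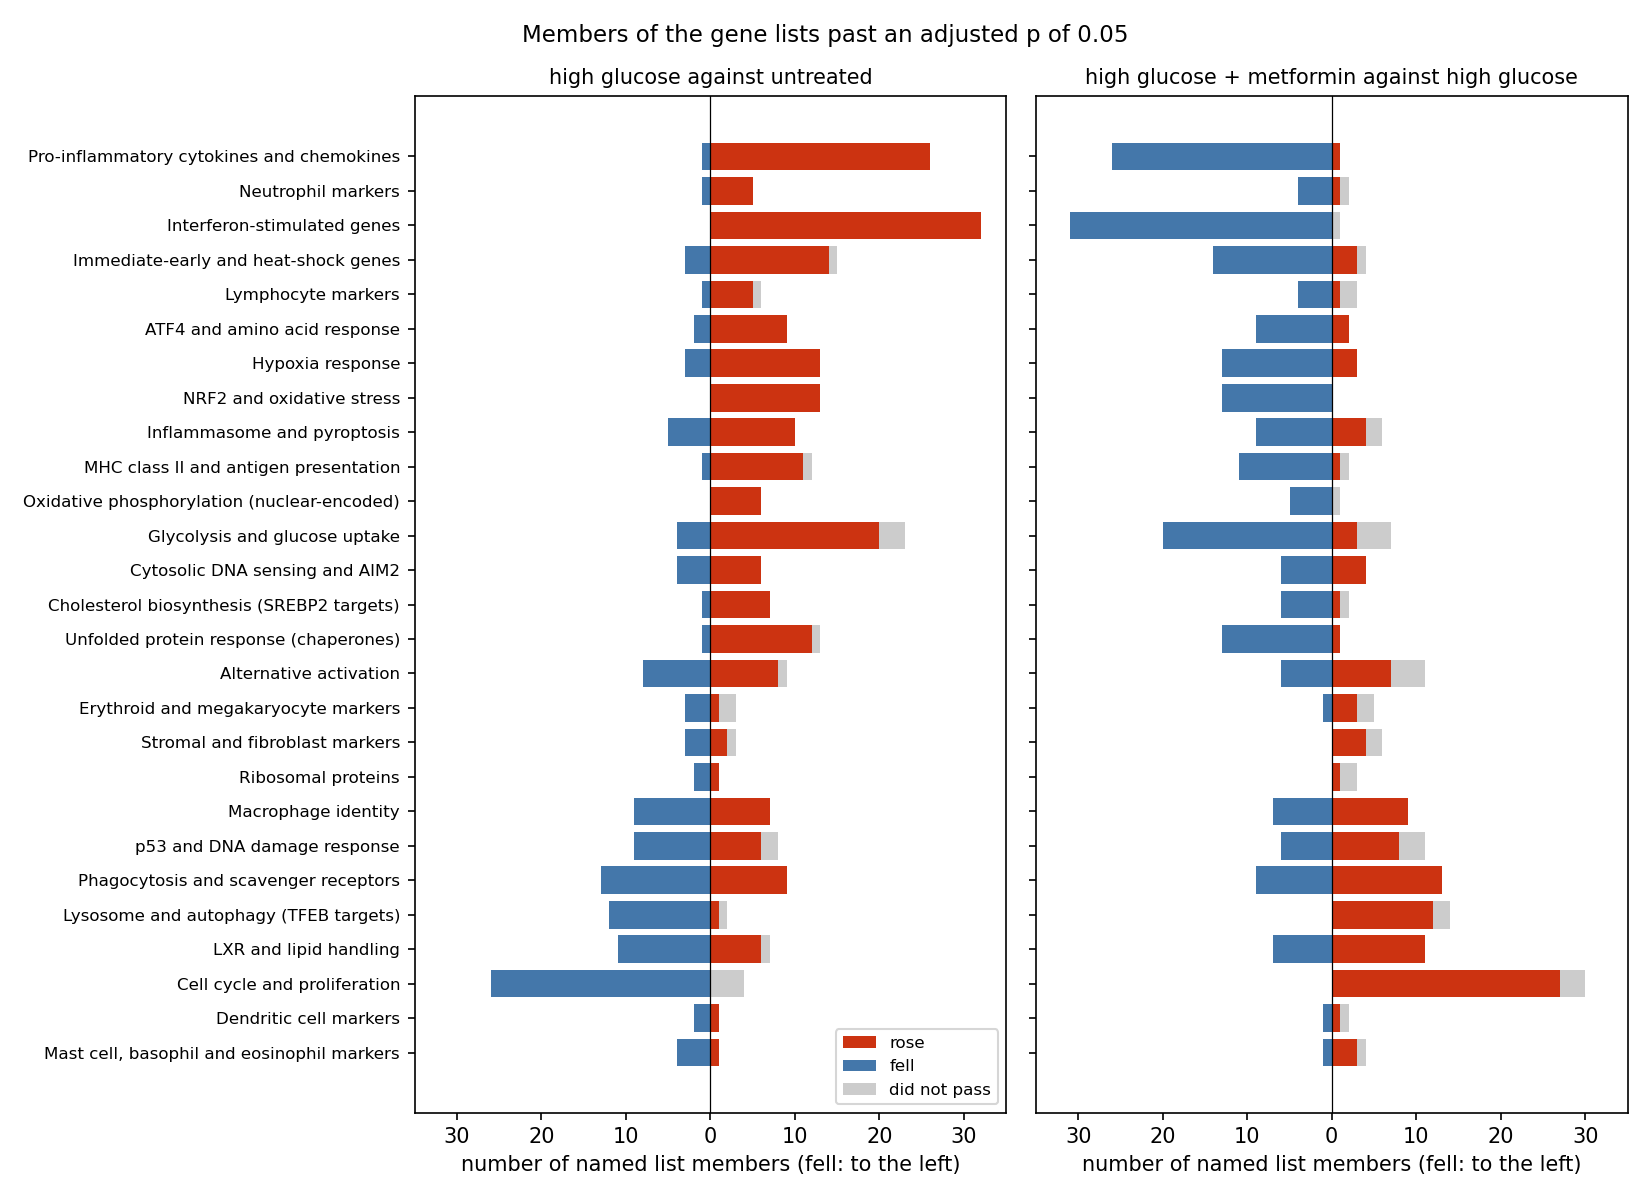
Number of named members (x axis) of each of 27 gene lists (y axis) that rose, fell or did not pass at an adjusted p of 0.05, with falls drawn to the left, for high glucose against untreated (left) and metformin with high glucose against high glucose (right). The 32 interferon-stimulated genes all rose in the left panel, and 31 of them fell in the right panel.

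Metformin in the presence of high glucose was compared with high glucose alone. Il1b was lower by a log2 difference of -11.46 (SE 0.834, adjusted p = 6.06e-05), from 15.4 ± 0.455 to 3.99 ± 0.759 (SD, n = 3), with 2 of the 3 metformin arrays under the low-signal level. Nos2 was at least 107-fold, Cxcl3 at least 139-fold, and Il6, a cytokine of the acute phase, at least 37.4-fold lower. Nlrp3 fell by 3.86 on the log2 scale (SE 0.113). Higher with metformin were Pparg, by 10.6-fold, the integrin subunit Itga6, by 12.2-fold (log2 change 3.61, SE 0.107), and Pcp4l1, by at least 14.1-fold.

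In this comparison 11803 probes were higher and 8855 lower (limma, adjusted p under 0.05), 23.5% of those tested, while cyclic loess scaling gave 10127 higher and 10322 lower, without the excess of rises. Among named genes, 2048 rose and 1803 fell, and with a fold of 2 or more 820 rose and 831 fell. In 38.2% of the probes the groups did not overlap, against 10% by chance. The falls selected by log2 difference also took in Lcn2 (-9.34, SE 0.317), Cxcl2 (-7.92, SE 0.443), Marco (-7.91, SE 0.234) and Tnfaip6 (at least 23.9-fold). The rises so selected also took in Mamdc2 (at least 12.1-fold), Ccsap (at least 4.05-fold), Nanos1 (at least 3.29-fold), Slc24a3 (at least 2.18-fold) and Slco2b1 (at least 1.68-fold). Marco had a metformin mean of 3.93, under the low-signal level, so the size of its fall is uncertain.

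In the list for cytosolic DNA sensing and AIM2, 6 genes fell and 4 rose with metformin. Zbp1 fell by 4.17 and Pyhin1 by 1.41 on the log2 scale, while Nlrc3 was 3.73-fold and Enpp1 3.03-fold higher (camera adjusted p = 0.448). In the inflammasome and pyroptosis list, 9 fell, 4 rose and 2 did not pass. Il1a fell by 4.81 and Gbp5 by 3.82 (camera adjusted p = 0.106). Gbp5 had a metformin mean of 3.98, under the low-signal level, so the size of its fall is uncertain. Gsdmd was lower by -0.62 on the log2 scale (SE 0.165, adjusted p = 0.0306). That call rested on each of 4 arrays: its adjusted p was 0.0694 and 0.09 without high-glucose replicates 1 and 2, and 0.0761 and 0.0961 without metformin replicates 1 and 2, with a range of 0.00343 to 0.0961 over all alternatives. With the replicate number as a block the adjusted p of Gsdmd was 0.0612, so the call was lost there too.

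Of 32 interferon-stimulated genes, 31 fell, Irf7 by 4.6, Ifit1 by 4.24 and Gbp6 by 3.22 on the log2 scale (camera adjusted p = 2.55e-11, and adjusted p = 0.116 with an estimated correlation). Of 27 cytokines and chemokines, 26 fell and Csf1 rose (camera adjusted p = 4.55e-09, and adjusted p = 0.116 with an estimated correlation). Of 18 immediate-early and heat-shock genes, 14 fell and 3 rose, with Nr4a2 lower by a log2 change of -4.8 and Nr4a1 by -3.13 (camera adjusted p = 0.00121, and adjusted p = 0.24 with an estimated correlation). Of 13 antigen presentation genes, 11 fell and 1 rose, with Psmb10 at -1.69 (camera adjusted p = 0.0115, and adjusted p = 0.324 with an estimated correlation). Of 27 glycolysis genes, 20 fell and 3 rose. Slc16a3 fell by 2.74 and Arrdc4 by 2.19, and Pdk4, the kinase that restrains pyruvate oxidation, was at least 4.03-fold higher (camera adjusted p = 0.00219, and adjusted p = 0.24 with an estimated correlation). All 13 NRF2 genes fell, Nqo1 by 3.86 and Sod2 by 3.34 (camera adjusted p = 5.19e-05, and adjusted p = 0.0813 with an estimated correlation).

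Of 16 hypoxia genes, 13 fell and 3 rose, with Vegfa at -3.17 and Hif1a at -1.99 (camera adjusted p = 0.0078, and adjusted p = 0.309 with an estimated correlation). Of 11 ATF4 genes, 9 fell and 2 rose, with Slc6a9 at least 17.9-fold lower (camera adjusted p = 0.0196, and adjusted p = 0.174 with an estimated correlation). Of 14 chaperone genes, 13 fell and 1 rose, with Hyou1 at -1.19 and Creld2 at -1.05 (camera adjusted p = 0.00313, and adjusted p = 0.24 with an estimated correlation). Of 6 oxidative phosphorylation genes, 5 fell, with Atp5o at -0.94 (camera adjusted p = 0.0253, and adjusted p = 0.24 with an estimated correlation). Of 8 cholesterol synthesis genes, 6 fell and 1 rose (camera adjusted p = 0.0546). Of 30 cell-cycle genes, 27 rose and none fell, with the anaphase activator Cdc20 3.32-fold and Cenpa 3.23-fold higher (camera adjusted p = 3.26e-05, and adjusted p = 0.24 with an estimated correlation). Of 14 lysosome and autophagy genes, 12 rose and none fell, with Fnip2 4.18-fold, Tfeb 2.6-fold and cathepsin Ctsl 2.13-fold higher (camera adjusted p = 0.00553, and adjusted p = 0.174 with an estimated correlation).

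The split lists split again. Alternative activation had 7 genes higher, such as the mannose receptor Mrc1 (4.51-fold), and 6 lower, such as Klf4 at -3.83. Phagocytosis had 13 higher and 9 lower, with C3 at -3.7 and Tlr2 at -2.94. LXR and lipid handling had 11 higher, among them Lpl (8.77-fold) and the ubiquitin ligase Mylip (6.84-fold), and 7 lower, among them Acsl1 at -2.9. The p53 list had 8 higher and 6 lower, with Sesn1 4.77-fold higher and Fas at -3.67, and here the median was 0.54 and the mean -0.07. None passed the list test (camera adjusted p between 0.321 and 0.753). Of the 3 ribosomal genes, Rpl4 rose 1.55-fold and 2 did not pass.

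Among cell-type markers, 9 macrophage identity genes rose and 7 fell, with Cebpa 5.55-fold higher (camera adjusted p = 0.624). Of 6 neutrophil markers, 4 fell and Csf3r rose, with Mmp9 at least 23.3-fold lower and S100a8 at -4.45 (camera adjusted p = 0.0388, and adjusted p = 0.24 with an estimated correlation). Of 7 lymphocyte markers, 4 fell and 1 rose, with Gzmb at -1.67. Of 5 mast cell, basophil and eosinophil markers, 3 rose and 1 fell, with Ccr3 2.62-fold higher. Of 6 stromal markers, 4 rose, with Bgn 1.74-fold higher. Of 6 erythroid and megakaryocyte markers, 3 rose and 1 fell, with Vwf 1.96-fold higher. The rises of Col5a1 and Epor and the fall of Klf1 lost their calls without single arrays (limma adjusted p up to 0.0736, 0.0594 and 0.0758). Of 3 dendritic markers, Bst2 fell by 2.3 and Itgax rose. The lymphocyte, mast cell, stromal and erythroid lists did not pass (camera adjusted p between 0.118 and 0.528). Adjusted over the list alone, the count past the threshold differed for inflammasome genes (15 of 15), interferon-stimulated genes (32 of 32), alternative activation (14 of 17), glycolysis (27 of 27), oxidative phosphorylation (6 of 6), p53 (15 of 17), cell cycle (29 of 30), lysosome (14 of 14), immediate-early genes (18 of 18), ribosomal genes (3 of 3), dendritic (3 of 3), lymphocyte (6 of 7) and stromal markers (6 of 6). The preset correlation passed 13 of 25 lists, 11 down and 2 up, and the estimated correlation none.

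The metformin and high-glucose changes were set against each other gene by gene. Across the 87955 probes, which are not independent replicates, their correlation was -0.862. Both comparisons share the 3 high-glucose arrays, which alone gives -0.5 in 100 simulations of unchanged groups. Their covariance was -0.533, against -0.0609 simulated, a difference of -0.472. Of 10365 probes that rose with high glucose, 7793 (75.2%) fell with metformin, where independent lists of these sizes would share 1044. Of 11806 that fell, 9483 (80.3%) rose with metformin, where independent lists would share 1584. In the same direction in both comparisons, 1 probe rose and 2 fell. Among named genes, 1677 of 1949 rose and then fell, and 1814 of 2117 fell and then rose. The expected overlaps of 1044 and 1584 leave the sharing out, while the covariance difference is net of its simulated size. With 3 arrays the shared group could not be split into parts of 2 or more. Part of the excess overlap may come from sharing, as may any covariance that the simulation misses.

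**Figure D3:**
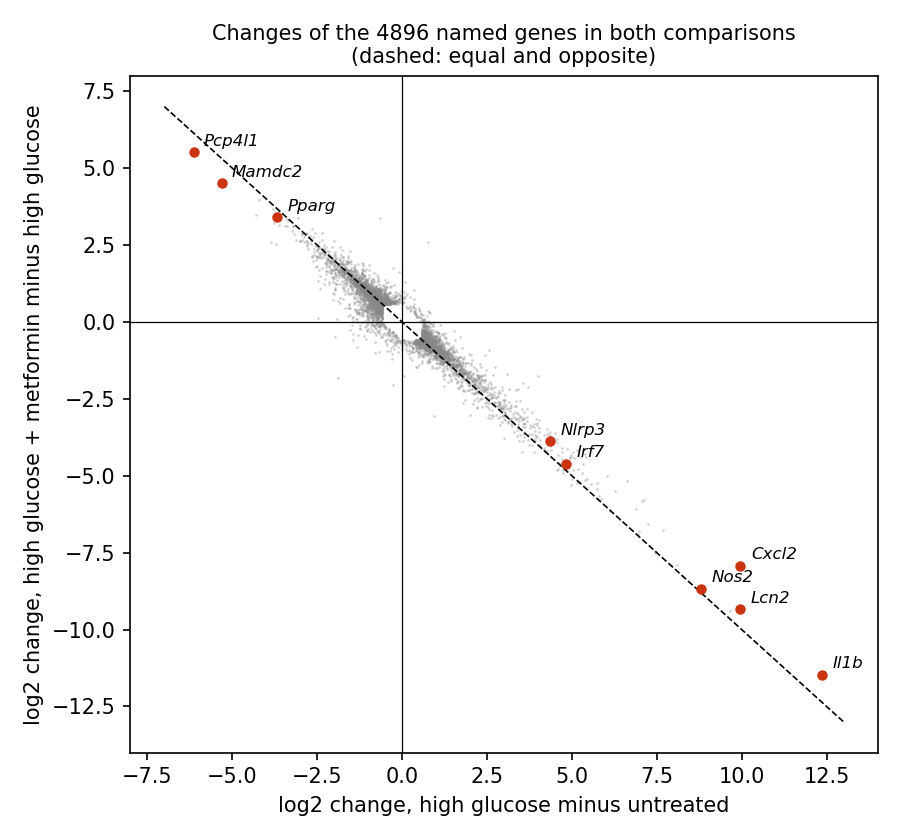
Log2 change with metformin (y axis) against log2 change with high glucose (x axis) for the 4896 named genes, each point a gene and the dashed line marking equal and opposite changes. Il1b lies at 12.38 and -11.46, and the gap around the origin follows from the selection of the named table.

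Metformin-treated cells under high glucose were then set against untreated cells. Only 5 probes were higher and 3 lower (limma, adjusted p under 0.05), and 7612 of 87955 had an unadjusted p under 0.05. In 18.2% of the probes the groups did not overlap, against 10% by chance. Of the 8 probes, 6 carry no gene name and have all group means under the low-signal level. The 1 named gene past the threshold was Fpr1, a formyl peptide receptor of phagocytes, which was higher with metformin by a log2 change of 1.45 (SE 0.122, adjusted p = 0.0407) and named here after its value was seen. No named gene passed with the 2 groups alone, the replicate number as a block, cyclic loess, or without any 1 of 8 of the arrays. The call of Fpr1 was lost there. Its log2 change with high glucose alone had been 6.62. A second named probe among the 8 belongs to Pde4b, a phosphodiesterase of cyclic AMP, at 1.07 (adjusted p = 0.0407), although it is not that gene's brightest. At an unadjusted p under 0.05, 1023 of 4896 named genes were called. That count is raised by construction, since the named table holds probes that differed in any comparison, this one included. For Il1b the difference was 0.92 (adjusted p = 0.76), for Nlrp3 0.48 (adjusted p = 0.368), for Gsdmd 0.14 (adjusted p = 0.812) and for Zbp1 0.2 (adjusted p = 0.629).

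No list had a member past the threshold in this comparison. Against the other named genes, interferon-stimulated genes (median 0.16, camera adjusted p = 0.0365) and cytokines and chemokines (median 0.2, adjusted p = 0.037) ranked higher, and chaperones of the unfolded protein response lower (median -0.15, adjusted p = 0.0365). With an estimated correlation their adjusted p were 0.724, 0.614 and 0.614. Against no change, by fry, these 3 lists did not pass (adjusted p = 0.0739, 0.066 and 0.0569), and NRF2 genes alone did (median 0.15, adjusted p = 0.000633). Adjusted over the list alone, 4 of 27 cytokine and chemokine genes passed, 2 genes each of the NRF2, inflammasome, phagocytosis, macrophage identity and dendritic cell lists, and 1 each of the alternative activation, p53 and neutrophil lists. The probe count depended on single arrays, from 0 without high-glucose replicate 1 to 53 without metformin replicate 1. Its balance turned as well, to 1 higher and 13 lower, 1 and 10, and 3 and 17 without untreated replicates 1, 2 and 3, and to 0 and 4 and 0 and 2 without high-glucose replicates 2 and 3. With a variance trend it was 78 higher and 13 lower.

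Over all 3 groups together, 20715 probes and 3997 named genes differed (limma F-test, adjusted p under 0.05). Among 47 probes whose symbol the reference annotation calls a non-coding gene or a pseudogene, 8 were higher and 23 lower with high glucose, and 21 were higher and 9 lower with metformin against high glucose. Between metformin and untreated cells none passed with limma, and 10 had an unadjusted p under 0.05. The 21 symbols include Slfn10-ps, by its symbol a schlafen pseudogene, lower by a log2 change of -1.68 with high glucose and higher by 1.61 with metformin, and the transcribed pseudogene Gm11787, at 2.27 and -1.79. Both were named after their values were seen.

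The deposited coordinates name no genome build in the sources used here, and are given as they stand. Of 13836 named rows whose symbol has a span in GRCm38.p6, 89.32% lay inside that span and 37.11% had the same start. Other builds were not compared. Il1b is placed on chromosome 2 from 129364578 to 129371139, Nlrp3 on chromosome 11 from 59542686 to 59566956, Gsdmd on chromosome 15 from 75862339 to 75867404, Zbp1 on chromosome 2 from 173213736 to 173218922, Nos2 on chromosome 11 from 78920787 to 78960226 and Pparg on chromosome 6 from 115362349 to 115490401. Whether a probe lies in an exon or an untranslated region is not given in the sources used here.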

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

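The tests of labelling, of a contaminant and of a batch in this part were chosen after the results were seen. Among 37 control spots with a mean of 4 or more, which enter no comparison, 12 had all 3 high-glucose arrays above the other 6. Of these, 10 are among the 11 spots named for the glycolytic enzymes GAPDH and PGK1. On the mouse spots for GAPDH the log2 difference between high glucose and untreated was 0.953 (13.2 ± 0.065 to 14.2 ± 0.14, SD, n = 3) and 1.266 (15.3 ± 0.061 to 16.6 ± 0.037), and for PGK1 0.995 and 1.342. With metformin they were lower than high glucose by -1.02, -1.2, -0.98 and -1.28. On the spots named for human sequences the difference was 1.289 and 1.044 for GAPDH and 0.781 and 1.239 for PGK1, and on those for rat 1.196 and 0.282 for GAPDH and 1.337 for PGK1. The remaining rat spot for PGK1 had a mean of 1.77, under the level of 4, and a difference of -0.337. The brightest named probe of Gapdh, looked up after these spots were seen, differed by 0.89 with an adjusted p of 0.0553 (limma). Of the remaining spots, 1 named E1A differed by 0.332 and 1 named DCP by 0.753.

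The high-glucose arrays stood apart from the other 6 on many probes: at a mean of 4 or more, 44.2% of probes had all 3 high-glucose arrays outside the range of the rest, where chance gives 2.4%. If labelling or hybridisation were the whole cause, control spots named E1A, DCP or ERCC, taken here as spike-ins although their names are not explained, should move alike. They did so in 8.3% (2 of 24). Their median absolute difference was 0.291, against 0.831 for called probes. Called probes were chosen for differing, so these 2 medians cannot be compared. Some of the 24 spots track each other across arrays, such as a DCP and an E1A spot with means of 12.222 and 12.239, and are not independent. Some bright ones also varied more within groups than probes did. That DCP spot had SDs of 0.323 untreated and 0.621 with metformin, while probes at 12 to 19 had a median of 0.099. Such spread can keep 3 arrays from lying outside the other 6. The shares of 8.3% and 44.2% thus do not decide about labelling or hybridisation as the whole cause. The spike-in differences ran from -0.304 to 0.753, and 21 of the 24 were higher in high glucose, so a shift of this kind stays open. A contaminant of the glucose medium that acted alike with and without metformin would leave the cytokine rise in place. A median of 4.5% of the log2 rise was left over 26 risen genes (range -23.1% to 41.7%). That form was already at odds with high-glucose arrays lying apart from the metformin arrays. The share left therefore restates that pattern and is no separate test of it. A contaminant whose effect metformin blocks, and a culture or RNA batch holding only the high-glucose samples, cannot be told apart from the treatment, since 0 batches are named by the labels or files. High glucose itself, which the design names, stays open beside them.

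Other splits of the arrays were tested with limma. With 10 splits of 6 arrays a share under 0.05 cannot be reached: for high glucose against untreated 1 split, the real one, gave 22171 probes and the highest other gave 1. For metformin against high glucose 1 split, the real one, gave 20658 and the highest other 2, and for metformin against untreated 1 split, the real one, gave 8 and the highest other 5. Over the 3 groups, 1 of 100 splits, the real one, gave as many as 20715 probes. A random choice of the 3 high-glucose arrays is thus unlikely there, while the labels of the other 6 are hardly tested. Chance differences between cultures cannot be excluded, since the replicates may be technical. The highest other, 19675, was the 1 drawn split that also kept the high-glucose arrays together, and the remaining splits gave at most 3.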

How the results depend on the processing

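Cyclic loess and the filter on the highest group mean were chosen after the data were seen. The values are already quantile normalized, so quantile normalization and median centring moved at most a few probes and say nothing about stability. Requiring a fold of 2 beside the adjusted p left 8672 probes and 1815 named genes for high glucose against untreated and 8024 and 1651 for metformin against high glucose. With an unadjusted p instead, the numbers were 10277, 1894, 9544 and 1700. Both fold rules ask for larger changes by construction. Under all other alternatives, these counts, those over 3 groups and those of non-coding probes stayed within 1.5 times, apart from the mean over a gene's probes, which merges the named probes by construction and left 5042 higher and 5626 lower for the first comparison and 5452 and 3973 for the other. Leaving out 1 array gave 16666 to 22275 probes for the first comparison and 16544 to 18882 for the other. Both highest counts came without high-glucose replicate 3. Lists past camera fell from 13 to 0 in both comparisons with an estimated correlation and were 24 with fry, which asks another question, and were 12 to 14 otherwise. The neutrophil list in the metformin comparison passed in 18 of 19 alternatives (highest adjusted p 0.051, lowest 0.0285) and the cholesterol list in 5 of 19 (0.0441 to 0.0706).

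For metformin against untreated the count of 8 probes and 1 gene moved most. Probes were 19 without a filter, 2 with either stricter filter, 91 with a variance trend, 20 with array weights, 0 with the 2 groups alone, and 8 and 1544 with a fold of 2 beside an adjusted or unadjusted p. Genes were 2 without a filter and with every probe on its own, 29 with a variance trend, 0 with the 2 groups alone and with cyclic loess, and 100 with a fold of 2 and an unadjusted p. With the replicate number as a block both were 0. Leaving out 1 array gave 0 to 53 probes and 0 to 8 genes (14 and 20 probes without untreated replicates 1 and 3; 0, 4 and 2 without high-glucose replicates 1, 2 and 3; 53, 3 and 4 without metformin replicates 1, 2 and 3). The cause was not tested.

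The reversal correlation was -0.937 with the 50th percentile filter and -0.939 with the filter on group means, where fewer noisy probes enter, and -0.785 with the mean over probes; without 1 array it was -0.879 to -0.819. Across 221 values of named genes, 4358 of 4407 recomputed values kept their direction and side of the threshold, 49 lost the call and none reversed. Many of these genes were chosen for large changes past the threshold, and quantile normalization and median centring are among the settings. Much of that agreement is therefore by construction. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.05 to 0.05, 6 of 9 arrays had a higher mean correlation with their own number than with the others, and the block took 22171 to 19107 and 20658 to 17471 probes. Beyond the counts against untreated, the block ended the calls of Gsdmd, Epor and Col5a1 with metformin. Low signal limits the calls: at means under 4, 14.3% of simulated 4-fold changes were recovered for high glucose against untreated.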

Other observations

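The gene families here were defined by symbol after the data were seen, and the tests of 11 of 12 were adjusted together. They hold named genes only, so family members without a probe that differed between groups could not appear. The 3 named formyl peptide receptors, of a family that senses bacterial and mitochondrial peptides, rose with high glucose. Their log2 changes were 7.07 for Fpr2, 7.14 for Fpr3 and 6.62 for Fpr1, and they fell with metformin by 5.83, 5.79 and 5.16. Of 12 C-type lectins, 8 rose and 2 fell with high glucose, among them Clec4e, a receptor for mycobacterial glycolipid, at 4.94 (camera adjusted p = 0.0514). Of 9 matrix metalloproteinases, 7 rose and 1, Mmp12, fell, with Mmp3 at least 1.67-fold higher (camera adjusted p = 0.0327, and adjusted p = 0.264 with an estimated correlation). Of 8 histone genes, 7 fell, such as Hist1h2bk at -1.77 (camera adjusted p = 0.0327, and adjusted p = 0.47 with an estimated correlation). Of 15 proteasome genes, 12 rose and 2 fell, with Psmd10 at 1.44 (camera adjusted p = 0.0327, and adjusted p = 0.47 with an estimated correlation). With metformin against high glucose the metalloproteinase, histone and proteasome families went the other way and did not pass (camera adjusted p = 0.0551 each), nor did the lectins (0.0624). Values within these families are uncertain, since close relatives can bind the same probe.

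Cytokine signalling inhibitors, integrins and transporters went both ways. Among 6 SOCS genes, 3 rose and 1 fell, with Cish at least 34-fold higher and Socs3 at 5.39. Of 17 integrins, 7 rose and 6 fell: Itga1 and Itgb8 were at least 8.31-fold and 2.79-fold higher while Itga6 fell by 3.62. Of 106 solute carriers, 48 rose and 45 fell. The dicarboxylate transporter Slc13a3 rose by 5.16, and Slc40a1, the iron exporter ferroportin, fell by 3.08 on the log2 scale. The 5 Toll-like receptors (3 up), 15 semaphorins and plexins (7 up), 14 TNF superfamily genes (8 up) and 6 SLAM family genes (3 up) also went both ways. None of these 7 families passed (camera adjusted p between 0.538 and 0.911).

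Few probes differed between metformin and untreated arrays, although the metformin arrays did not lie where left-out untreated arrays did. The tests of power and of mixed-up RNA were chosen after the result was seen. In simulated data 92.9% of 4-fold changes at a mean of 4 or more were recovered for this comparison, which argues against too few arrays as the reason at that size. At the same signal 50% of 2-fold and 0 of 38 changes of 1.5-fold were recovered, so smaller differences stay open. If metformin arrays had been hybridised with RNA of the same untreated cultures, they should lie where untreated arrays lie on the line from untreated to high glucose. With each untreated array left out of the probe choice and of the line, it lay at 4.07% of the way (SD 0.23, n = 3). The metformin arrays lay at 11.3%, a mean difference of 7.19 points and a smallest of 6.61. The same RNA labelled or hybridised apart could also be displaced along this line, so the difference does not decide about that mix-up. RNA of other untreated cultures, or another batch, cannot be told apart from a small remainder of the high-glucose state, since metformin and untreated arrays correlated at a median of 0.9743, against 0.9719 between metformin arrays.

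With high glucose, 272 risen and 303 fallen named genes were not called with metformin, and 360 were called with metformin alone. These counts come from thresholds, and the differences behind them were not tested.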
